A study of Bos taurus with 12 samples.

How the data were processed

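Whole blood was taken from 12 dairy cows of one herd, and the methylation of genomic DNA was read by enzymatic methylation sequencing. Per the labels' protocols, TET2 and T4-BGT protected methylated and hydroxymethylated cytosines, APOBEC3A turned the remaining cytosines into uracils, and these were read as thymines after amplification. Both modified forms of cytosine therefore count as methylated. A thymine present in a cow's own genome is read in the same way as an unmethylated cytosine, so a sequence variant at a cytosine can lower a methylation value. Per the labels, MSG held 6 cows that left the herd within 1 year because of mastitis complications unknown at sampling, and MRG held 6 cows of similar age that were still in the herd. Replicate numbers only name the cows within a group, in the order of the sample records, and pair no cows. The labels gave no batch, parity, breed or blood cell count.

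The submitters' processing notes named fastp 0.23.1, Bismark, DRAGEN and ChIPseeker 1.32.1, with no role or order, and the genome build ARS-UCD1.2. The differential test and the annotation release were not given in the sources used here. The authors deposited percent methylation per cow in 2 tables, per the file headers. One listed single CpG cytosines by strand (sites, 196275 rows), and the other listed windows of 500 bases that started every 250 bases (tiles, 1227 rows). The deposited tables also held the authors' difference in percentage points, the authors' p-value and q-value, the nearest gene, the annotation class and the distance to the transcription start, per the file headers. In the authors' deposited tables the smallest absolute difference was 25 points in both, and the largest q-value was 0.01 among sites and 2.23e-08 among tiles. Every row had thus been selected on these same cows before it was tested again here. The retest is not independent evidence, and sites that missed the authors' thresholds were not analysed here, so no enrichment over the covered genome was tested.

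The tile table held 36 further columns of coverage and of converted and unconverted reads whose names carried numbers rather than cows. They could not be tied to cows by name and were not used. Depth was therefore not used for either table, no interval for sequencing depth is given, and the logistic test on read counts foreseen for tables with counts was replaced by the test foreseen for percent values. Each listed row had a value for at least 5 cows of each group, and 161217 sites and 982 tiles had a value for all 12 cows.

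Each site and each tile was tested for MSG against MRG with limma 3.58.1 in R 4.3.3 on percent methylation, 1 value per cow and no covariate, two-sided, with Benjamini-Hochberg adjustment over the rows of its table and a threshold of 0.05. An exact permutation test of the difference of means over all 924 regroupings of the cows was the alternative test. For 6 cows against 6 the smallest p it can give is 0.00216. The limma code was tested on simulated data with the observed spread of each row and 200 changed rows. The simulated values were independent normal draws around 50%, without the pile-up at 0 or the correlation of neighbours in the listed rows. Among tiles it recovered 9% of differences of 25 points, 48.5% of 35 points and 89.5% of 50 points. Among sites it recovered 0% at 25, 35 and 50 points, while an unadjusted p under 0.05 was reached by 48%, 56.5% and 83% of the changed sites.

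The share of rows higher in MSG was given with an interval (95%) from 2000 bootstrap draws of blocks of 1 Mb. This interval covers the spread over the genome with the cows held fixed, and not the spread between cows. Promoter sites were compared with other sites by 10000 permutations of the promoter mark between runs of sites closer than 1 kb, two-sided. The 16 gene lists, 10 of pathways and 6 of blood cell markers, were compared with 10000 random sets of as many listed genes, two-sided, with Benjamini-Hochberg adjustment over lists, and lists with fewer than 3 genes in a setting were left out of it. Their members were fixed before the data were examined. Numbers of list genes with a site were not compared with length-matched genes, since no annotation of the same build was used. Gene names came from the deposited tables; the names table used here belongs to the assembly ARS-UCD2.0, added 0 symbols, and gave no coordinates. It lacked 10 of the 470 list genes. One gene in which a single cow stood apart is not reported here, although the counts of such groups include it. No symbol was given for 49913 sites (25.4%) and 387 tiles.

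The genes named were chosen by a rule fixed before the data were examined. Among tiles with a symbol and no overlap between the groups' cows, it took the 6 largest differences in each direction, 1 per gene. Among genes with 3 or more listed promoter sites of one direction, it took the 4 with the most in each direction. Among genes with 10 or more sites it took the 3 with the most sites per kb of gene in each direction, counted here inside the gene and assigned by the majority of sites. From each list it took up to 3 members with the most sites, those with a tile first. For a named gene, the sites of its more frequent direction were averaged per cow, and the exact permutation p was adjusted over the 66 genes so treated. That average takes up only sites already selected for their direction, so its p describes the spread between cows and is no evidence that the gene differs.

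The alternatives fixed beforehand were a logit scale with an offset of 1 point, the exact permutation test, rows with all 12 cows, each cow left out in turn, a threshold of 0.01, a difference of at least 40 points, an authors' q-value under 0.001, 1 site per run, autosomes only, promoters within 1 kb, at least 3 sites per tile, lists without distal intergenic sites, promoter sites only and 1 vote per gene. Leaving out rows with a cow at exactly 0 and counting each CpG once were chosen after seeing the data. Further tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.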

Results

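Methylation of blood DNA was measured in 12 dairy cows to ask whether it differed, up to 1 year ahead, between cows later culled for complications of mastitis (MSG, 6 cows) and cows that stayed in the herd (MRG, 6 cows). Mastitis is an infection or inflammation of the udder. Values are percent methylation per cow at 196275 CpG cytosines (sites) and 1227 windows of 500 bases (tiles) that the authors had listed as different between the groups. The depth behind each value was not used, and precision was judged from the spread between cows. Averaged over the listed sites, MSG cows stood at 54.6% ± 0.485 and MRG cows at 52.9% ± 0.75 (SD, n = 6 each). Over the tiles the means were 56.9% ± 1.02 in MSG and 53.7% ± 0.412 in MRG. Both pairs of means rest on rows chosen for their difference.

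Of the 196275 sites, 103532 were higher and 92743 lower in MSG, a share of 52.7% higher with a block bootstrap interval of 51.8% to 53.7%. Of the 1227 tiles, 690 were higher and 537 lower in MSG, a share of 56.2% with an interval of 51.8% to 60.4%. Both intervals leave out the spread between cows. Chromosome 1 held the most sites, 17742, of which 51.3% were higher in MSG. Chromosome 4 had 59.9% of its 6362 sites higher in MSG, and chromosome 2 had 45.5% of its 13346 sites higher. At a difference of 40 points or more, the share of sites higher in MSG was 50.9% and its interval, 49.1% to 52.7%, took in an even split. For the 46 tiles of that size the share was 54.3%, with an interval of 39.1% to 69.4%.

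Most listed sites lay away from genes. Distal intergenic sequence held 114285 sites (58.2%), introns 68515 (34.9%), promoters 10676 (5.44%), exons 1850, 3' untranslated regions 752, and 5' untranslated regions 15. Among tiles, 832 were distal intergenic, 333 intronic, 52 in promoters, 7 in exons and 3 in 3' untranslated regions. Promoter sites were higher in MSG in 54.4% of cases and other sites in 52.7%, a difference of 1.76 percentage points. The test marked whole runs by the majority of their sites, and by runs the difference was 2.06 points (permutation p = 0.0125, two-sided). It holds the cows fixed and leaves out the spread between them. The difference did not hold with promoters limited to 1 kb around the start (-0.547 points, -0.143 by runs, permutation p = 0.924). It did not hold when each run of sites counted once (0.668 points, permutation p = 0.322). Nor did it without sites at which a cow was at exactly 0 (-1.25 points, -1.07 by runs, permutation p = 0.460).

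Listed sites and tiles pointed the same way. Of the 1227 tiles, 1200 held at least 1 listed site, and in all 1200 a site of the tile's direction was present. Both tables came from the same reads, so this describes the tables and is no second measurement. Overlapping tiles merged into 1002 regions.

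Tiles were named from those with a symbol and no overlap between the groups' cows, as the 6 with the largest difference in each direction. ENOPH1 encodes an enzyme of the methionine salvage pathway, and its promoter tile (chromosome 6, 97218251 to 97218750, ARS-UCD1.2, 1.06 kb inside the gene from the start) stood at 1.37% ± 0.725 in MSG and 34.8% ± 7.67 in MRG (SD, n = 6 each). An intronic tile of IGSF21, which encodes an immunoglobulin superfamily protein (chromosome 2, 134343251 to 134343750), stood at 24.4% ± 4.83 in MSG and 67.9% ± 21.7 in MRG. An intronic tile of the receptor tyrosine kinase gene EPHB2 (chromosome 2, 129963751 to 129964250) stood at 28.6% ± 16.2 in MSG and 61.4% ± 12.5 in MRG. In an intron of MGAT5, a glycosyltransferase gene, the tile at chromosome 2, 63077751 to 63078250, stood at 48.7% ± 10.5 in MSG and 83.2% ± 10.2 in MRG.

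The other tiles lower in MSG were intergenic. The tile 7.0 kb from MTMR9 (chromosome 8, 8071001 to 8071500) stood at 24.5% ± 3.97 in MSG (n = 5) and 55.7% ± 6.04 in MRG (n = 6). The tile 52.7 kb from FTH1, the ferritin heavy chain gene (chromosome 29, 40533001 to 40533500), stood at 63.2% ± 14.8 in MSG and 92.4% ± 4.61 in MRG (n = 5 each). Of the tiles higher in MSG, those nearest to olfactory receptor genes were a promoter tile of OR8B1ASP (chromosome 9, 104438001 to 104438500), at 48.0% ± 8.93 in MSG (n = 6) against 16.7% ± 10.5 in MRG (n = 5), and an intergenic tile 31.4 kb from OR8B1R (chromosome 29, 27363001 to 27363500), at 52.5% ± 7.17 against 18.9% ± 7.88 (n = 6 each). Among these named tiles the widest difference upward was 42.5 points, at an intergenic tile 20.3 kb from LOC112447179 (chromosome 6, 2751751 to 2752250), with 67.8% ± 15.7 in MSG and 25.3% ± 9.30 in MRG. The intergenic tile near LOC505199 (chromosome 10, 38902001 to 38902500) stood at 84.9% ± 2.48 and 48.5% ± 16.5, and the promoter tile of LOC112449036 (chromosome 12, 16903001 to 16903500) at 81.1% ± 5.71 and 46.5% ± 17.0 with 5 MRG cows. An intergenic tile 254 kb from LOC112443267 (chromosome 21, 62728001 to 62728500) stood at 69.0% ± 9.13 and 37.1% ± 21 with 5 cows per group.

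**Figure D1:**
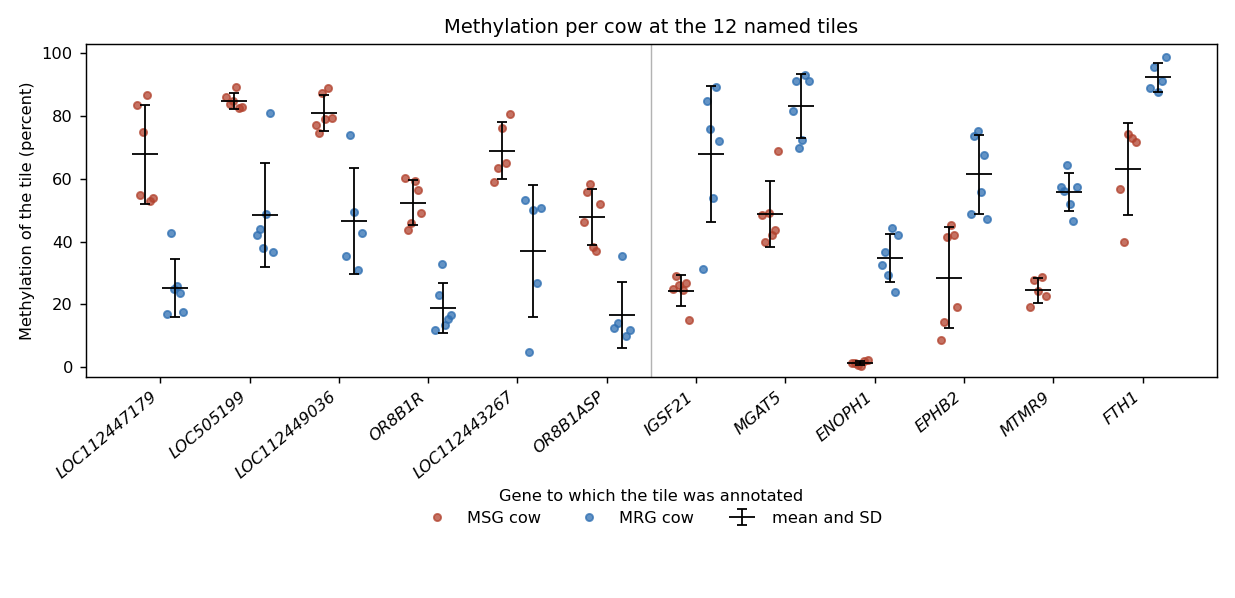
Percent methylation (vertical axis) of the 12 tiles named by the fixed rule (horizontal axis, by annotated gene); each point is 1 cow, red for MSG and blue for MRG, and bars show the mean and SD. The 6 tiles on the left were higher and the 6 on the right lower in MSG, with no overlap between the groups' cows by the rule of choice, and all 6 MSG cows lay near 1.37% at ENOPH1.

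Each of these 12 tiles passed the limma test at an adjusted p of 0.0347, which is the lowest of all listed tiles. The exact permutation test gave them adjusted p values of 0.0422 to 0.0499. With no overlap between the groups' cows its unadjusted p is fixed at the lowest it can give, so that result restates the rule of choice. The same rule favours a low p in limma's test. With a cow left out, limma's adjusted p of the tile near FTH1 was 0.0506 without MSG replicate 1 and 0.0589 without MSG replicate 3, and that of the tile near LOC112443267 was 0.0544 to 0.0614 without MSG replicate 3 or 6 or MRG replicate 2 or 5. In all, 899 of the 1227 tiles passed limma's test, 511 higher and 388 lower in MSG, and 1025 had an unadjusted p under 0.05. The median spread between cows of one group was 19 points against a median absolute difference of 27.7 points. The groups' cows did not overlap in 74 tiles (6.03%), 45 higher and 29 lower in MSG. The count varied with the test: the exact permutation test passed 213 tiles, and a threshold of 0.01 passed 0. It was lower whichever cow was left out, from 397 to 797. It was 469, 498, 397 or 488 without MSG replicate 1, 2, 3 or 6 and 447, 457 or 449 without MRG replicate 1, 2 or 5. Whether this reflects single cows or the loss of any cow was not tested. All rows had been selected on these cows, so the count does not estimate how many tiles differ.

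At single sites, the median spread within a group was 27.7 points and the median absolute difference 32.7 points. None of the 196275 sites passed limma's test (lowest adjusted p = 0.0781), although 101964 had an unadjusted p under 0.05, and 0 passed the exact permutation test, where 69607 had an unadjusted p under 0.05. Without MSG replicate 6 the limma count was 74, and without MSG replicate 4 it was 1. The groups' cows did not overlap at 4635 sites (2.36%), 2730 of them higher and 1905 lower in MSG. At 153608 sites (78.3%) at least 1 cow was listed at exactly 0. Of the 42667 sites with no cow at 0, a set chosen after seeing the data, 31207 passed limma's test, 18108 higher and 13099 lower in MSG.

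**Figure D2:**
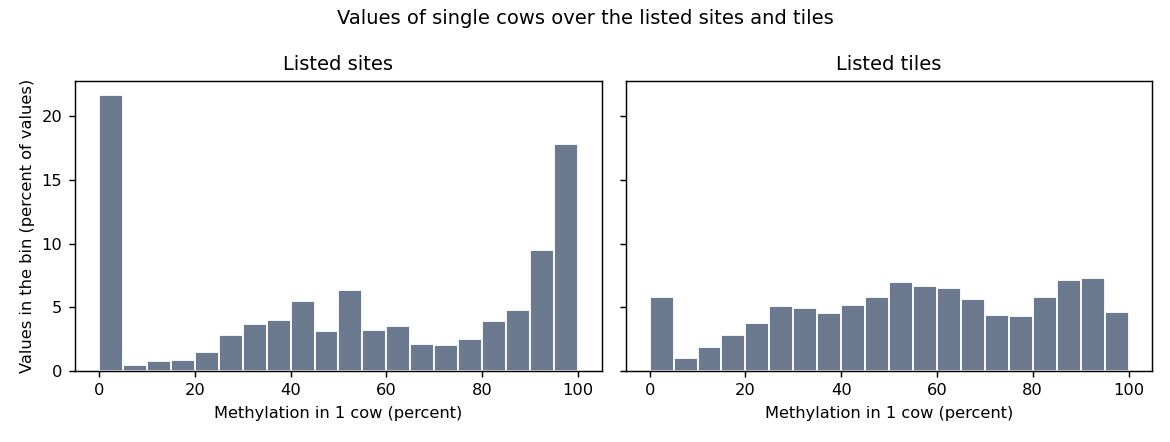
Distribution of the values of single cows over the listed sites (left) and tiles (right); the horizontal axis gives percent methylation in bins of 5 points and the vertical axis the percent of all values in the bin. Among sites, 21.7% of values were exactly 0 and 0.588% lay above 0 and up to 10%, while 5.21% of tile values were exactly 0.

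Promoters in which all listed sites pointed one way numbered 311 higher and 259 lower in MSG, among 931 genes with at least 3 listed promoter sites. For RYR2, a calcium release channel gene of heart muscle (chromosome 28), 31 promoter sites averaged 90.5% ± 1.14 in MSG and 54.5% ± 33.4 in MRG (SD, n = 6 each). For MYL10, a myosin light chain gene (chromosome 25), 24 promoter sites averaged 61.0% ± 26.5 and 10.5% ± 2.87. The microRNA gene MIR10165 (chromosome 26) had 21 such sites at 50.8% ± 34.5 and 6.51% ± 15.6, and the ephrin receptor gene EPHA8 (chromosome 2) had 16 at 72.7% ± 17.5 and 32.6% ± 28.7. In the other direction, 22 promoter sites of ENOPH1 averaged 1.41% ± 0.856 in MSG and 39.1% ± 6.19 in MRG. TBCK (20 sites, 58.7% ± 35.7 against 89.2% ± 20.3), TMCO4 (17 sites, 4.26% ± 4.93 against 42.3% ± 32.6) and CDA, which encodes cytidine deaminase (15 sites, 32.4% ± 38.9 against 80.1% ± 25), were the others with the most promoter sites lower in MSG. In RYR2, TBCK, TMCO4, CDA, MYL10, MIR10165, EPHA8 and ENOPH1 at least 84.8% of a gene's listed sites had a cow at exactly 0.

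Among genes with a symbol and at least 10 listed sites inside them, listed sites were densest in ENOPH1, where 102 sites lay inside the gene (chromosome 6, 97217195 to 97255729), 2.65 per kb. Its 98 sites lower in MSG averaged 4.96% ± 7.35 in MSG and 48.2% ± 1.28 in MRG, and at 95.1% of its sites a cow was at exactly 0. EPHA8 held 73 sites, 2.5 per kb, and all 90 sites annotated to it were higher in MSG. TMEM18 and TMEM19 followed with 2.44 and 2.11 sites per kb, 45 of 54 and 52 of 56 of their sites being higher in MSG. IL10RB, which encodes a subunit of the interleukin 10 receptor, held 1.95 sites per kb in the gene model of 21.5 kb given for most of its sites and 0.726 in a model of 71.6 kb given for 1 site, and the mitochondrial glutaredoxin gene GLRX5 held 1.91. Of their sites, 51 of 53 and 46 of 47 were lower in MSG.

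Immune genes were examined through 10 pathway lists. No list stood apart from random sets of as many listed genes after adjustment, and the direction of a list's sites differed from list to list. Of 125 sites of 18 antigen presentation genes, 35 were higher and 90 lower in MSG, which left 28.0% higher against 52.7% for other genes (p = 0.0249, adjusted p = 0.320, permutation of gene sets). Without sites at which a cow was at exactly 0, 12 of 20 of its sites were higher (60%, against 57.3% for other genes). Of 142 sites of 17 imprinted genes, which are expressed from one parental copy, 109 were higher (76.8%, p = 0.0400, adjusted p = 0.320, permutation of gene sets). In the remaining 8 pathway lists the share higher in MSG ran from 43.5% for NF-kappaB and JAK-STAT signalling to 61.4% for complement and antimicrobial proteins, with adjusted p of 0.593 or more. The share for complement and antimicrobial proteins was 31.7% of 41 sites without those with a cow at 0, and 46.7% with 1 vote per gene. Over 5 settings, 12 of the 16 pathway and marker lists passed from one side of the other genes' share to the other in at least 1, 10 of them without sites with a cow at 0. Imprinted genes and the monocyte, B cell and NK cell markers kept their side in every setting that held them. For NK cell markers without sites with a cow at 0 that was a near tie. The share was 57.9% of 19 sites against 57.3% for other genes, with 2 genes mostly higher and 4 mostly lower. Of the 470 list genes, 273 had a listed site. Sites were assigned to genes by the authors' annotation and mostly lay outside them: of 1914 sites of the 48 genes named from the lists, 452 (23.6%) lay inside the gene. None did for CXCR4, SOCS6, DLK1, CDKN1C and BOLA-NC1, and only 1 of 28 for TLR4, 1 of 15 for TRAF6, 1 of 14 for BOLA-DMB, 3 of 60 for MASP1 and 5 of 122 for TGFBR2, so their values describe sequence around or beyond these genes.

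Antigen presentation genes were represented by the class II genes BOLA-DYA and BOLA-DMB on chromosome 23. BOLA-DYA had 31 of 32 sites lower in MSG, averaging 25.2% ± 25 against 64.2% ± 36.6 in MRG, and BOLA-DMB had 13 of 14, at 24.9% ± 19.3 against 56.5% ± 32.1 (SD, n = 6). The class I gene BOLA-NC1 had 12 of 15 lower sites, at 55.2% ± 37.3 against 83.1% ± 13.9. For these class II and class I genes the exact permutation p adjusted over named genes was 0.0647, 0.0702 and 0.118. Lower sites with no cow at 0 numbered 1 for BOLA-DYA, 1 for BOLA-DMB and 2 for BOLA-NC1. Over these the exact permutation p was 0.0374, 0.0478 and 0.0248, adjusted over the 36 named genes with such sites. Each of the 3 genes also had sites with no cow at 0 that were higher in MSG, which this p leaves out. It rests on 1 or 2 sites picked for their direction and says nothing about the direction of these genes. Among imprinted genes, 20 of 25 sites of DLK1 were higher in MSG and averaged 91.8% ± 4.46 against 55.5% ± 14.3 in MRG, with 20% of its sites having a cow at 0. CDKN1C had 18 of 20 sites higher, at 76.3% ± 19.4 against 37.2% ± 10.9, and GRB10 had 19 of 23, at 56.8% ± 27.3 against 24.4% ± 14. With 1 vote per gene, 14 of 15 imprinted genes were mostly higher in MSG (adjusted p = 0.0528, permutation of gene sets).

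Cytokine and chemokine genes had many sites of both directions. Of 533 sites of 37 cytokine and cytokine receptor genes, 43.7% were higher in MSG. TGFBR2, a receptor of transforming growth factor beta, had 101 of 122 sites lower in MSG, at 26.9% ± 18.8 against 63.5% ± 25.7 in MRG, and 5 tiles, while IL5RA had 64 of 68 higher, at 55.4% ± 32.0 against 22.1% ± 19. Of 318 sites of 24 chemokine genes, 49.4% were higher. CXCR4, the receptor that retains leukocytes in bone marrow, had 101 of 171 sites lower, at 28.1% ± 11.1 against 66.1% ± 11.7, and all 171 were distal. CXCL12, its ligand, had 22 of 35 sites higher (66.5% ± 14 against 35.2% ± 25.2), and CXCL13 had 21 of 25 higher (74.4% ± 13.4 against 42.1% ± 13.8). A cow was at exactly 0 at 94.3% of the sites of TGFBR2, 98.5% of IL5RA, 83.0% of CXCR4 and 40% of CXCL13. Among sites with no cow at 0, most of TGFBR2 and CXCR4 were higher in MSG and most of CXCL12 lower. Most of those of CXCL13 stayed higher.

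Innate sensing and signalling genes showed a like mixture. Of 102 sites of 20 pattern recognition genes, 53.9% were higher in MSG, with TLR4, the receptor for bacterial lipopolysaccharide, at 58.9% ± 21.7 against 23.0% ± 18.3 over 20 of its 28 sites. TRAF6 stood at 60.8% ± 30.8 against 23.3% ± 22.2 over 13 of 15 sites and TLR3 at 64.6% ± 16.4 against 37.2% ± 19.3 over 10 of 14. In NF-kappaB and JAK-STAT signalling, TNFAIP3, an inhibitor of NF-kappaB, had 60 of 75 sites lower in MSG (17.7% ± 15.8 against 55.0% ± 19.9). SOCS6 had 60 of 71 lower (25.1% ± 18.8 against 60.5% ± 16.4) and MAP3K7 had 24 of 29 higher (39.5% ± 23.5 against 13.0% ± 15.7). All sites of TNFAIP3 and 98.6% of those of SOCS6 had a cow at exactly 0. Of 251 sites of 18 complement and antimicrobial genes, MASP1 held 60, of which 45 were higher in MSG (51.8% ± 31.3 against 8.21% ± 17.7). At 76.7% of the sites of MASP1 a cow was at exactly 0, and its other sites were all lower in MSG. The neighbouring genes C8B and C8A of the membrane attack complex had 52 of 88 sites higher and 11 of 19 lower. Among 224 sites of 26 adhesion and migration genes, 50.4% were higher. ARHGAP15 had 38 of 46 lower, DOCK2 15 of 21 higher and JAM2 26 of 36 higher. At 84.8% of the sites of ARHGAP15 a cow was at exactly 0, and most of its other sites were higher in MSG.

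The smaller lists gave shares of 46.1% for DNA methylation enzymes and related proteins and 47.8% for mammary and milk genes. ZBTB38, which binds methylated DNA, had 14 of 21 sites lower in MSG (38.8% ± 17.3 against 74.5% ± 12.8), TET3 had 15 of 20 higher and MBD2 had 9 of 17 higher. Among mammary and milk genes, NPFFR2 had 68 of 93 sites lower in MSG, at 35.8% ± 23.9 against 73.2% ± 5.31, and 2 tiles. At 87.1% of its sites a cow was at exactly 0, and most of its other sites were higher in MSG. ABCG2, a transporter that secretes compounds into milk, had 13 of 15 sites higher, at 93.1% ± 0.955 against 60.8% ± 19.9, and SLC4A4 had 10 of 17 higher. Per site, 0 sites of any list passed limma's test over all listed sites. When adjusted over the list alone, 308 sites passed in 9 of the 16 lists, 150 of them in erythroid and platelet markers, 82 in complement and antimicrobial genes, 42 in chemokines and 24 in imprinted genes. These sites had been selected on the same cows, and neighbouring sites are not independent. GYPC held 162 of the 199 sites of erythroid and platelet markers. Over its sites lower in MSG the exact permutation p adjusted over named genes was 0.0702.

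**Figure D3:**
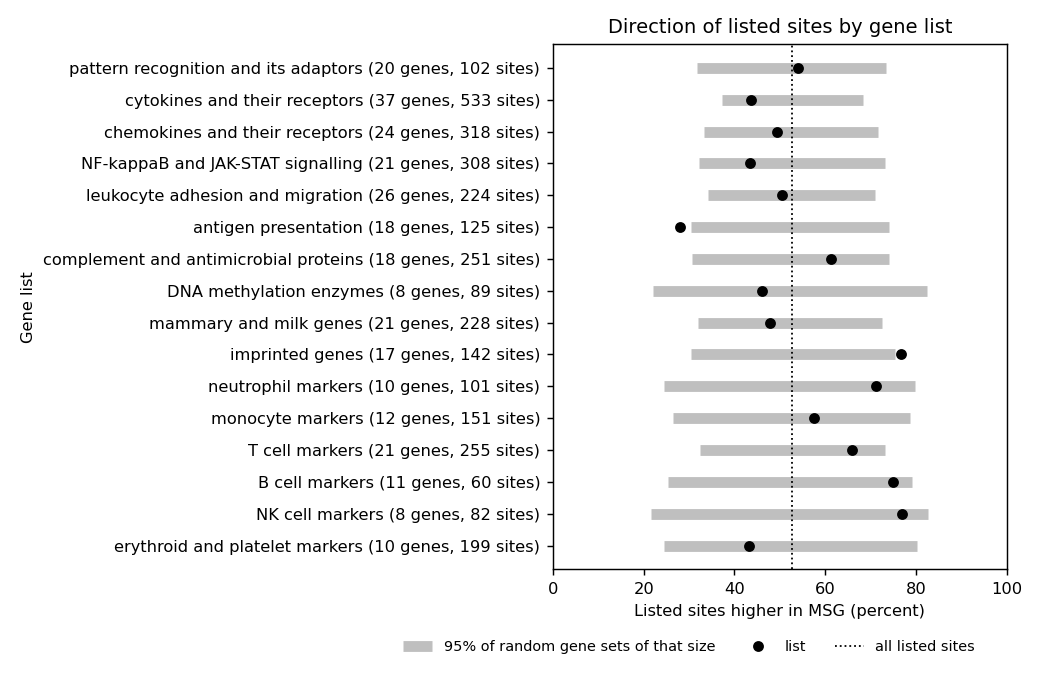
Percent of listed sites higher in MSG (horizontal axis) for each of the 16 gene lists (vertical axis, with its genes and sites); points are the lists, grey bars hold 95% of 10000 random gene sets of that size, and the dotted line marks all listed sites. Antigen presentation (28.0%) and imprinted genes (76.8%) lie outside their bars, and neither passed after adjustment over the lists.

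Blood holds several cell types whose proportions could differ between cows, and 6 marker lists were described for this reason. Sites higher in MSG made up 76.8% of 82 sites in NK cell markers, 75% of 60 in B cell markers, 71.3% of 101 in neutrophil markers, 65.9% of 255 in T cell markers, 57.6% of 151 in monocyte markers and 43.2% of 199 in erythroid and platelet markers. None stood apart from random gene sets (adjusted p of 0.537 to 0.847 over these lists, permutation of gene sets). Without sites at which a cow was at exactly 0 the share was 46.8% for T cell and 50% for neutrophil markers, against 57.4% for other genes. It was 57.9% both for NK cell markers and for erythroid and platelet markers. For T cell markers it was 42.9% with 1 vote per gene (9 genes higher, 12 lower) and 14.3% over 14 promoter sites. For erythroid and platelet markers these were 20% (2 genes higher, 8 lower) and 100% of 5 promoter sites. Among the markers, the NK cell receptor gene NCR1 had 11 of 14 sites higher (86.4% ± 4.10 against 42.3% ± 24.5), the T cell factor gene BCL11B 23 of 27 (90.9% ± 0.422 against 59.2% ± 31.6) and the monocyte scavenger receptor gene CD163 25 of 26 (93.9% ± 2.09 against 65.1% ± 27.3). The monocyte lectin gene CLEC4E went the other way, with 16 of 20 sites lower (52.7% ± 35.3 against 86.1% ± 17.3), and by genes the monocyte list had 7 mostly higher and 5 mostly lower and the neutrophil list 5 and 4. A cow was at exactly 0 at 92.9%, 74.1% and 3.85% of the sites of NCR1, BCL11B and CD163. LEF1 and THEMIS in T cells had 54 of 69 and 50 of 69 higher. BANK1 in B cells had 19 of 25 higher and NCF4 in neutrophils 30 of 36. The glycophorin gene GYPC had 92 of 162 lower, with 8 tiles. Of the other named genes of its list, VWF had 10 of 17 lower and SPTB 5 of 5 higher. At 58.8% of the sites of VWF a cow was at exactly 0, and its other sites were all higher in MSG. Per cow, the median over a list's sites was 86.4% ± 3.13 in MSG and 50.3% ± 7.43 in MRG for B cell markers, and 77.8% ± 5.45 and 46.0% ± 14 for NK cell markers (adjusted exact permutation p = 0.00649 for each, n = 6). For T cell, neutrophil, erythroid and monocyte markers that p was 0.0346, 0.0519, 0.0753 and 0.333. These medians are taken over sites chosen for a difference and follow each list's more frequent direction.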

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

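Of the tests reported in this part, those of the random-mating shares, of neighbouring sites, of the simulated differences and of other splits of the cows were chosen after the result was seen. The tests of sites within tiles and of the authors' p values against the spread between cows were written down beforehand.

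Single cows stood far from the rest of their group in 29 of 174 groups of values examined by Dixon's ratio. Chance gives about 1 in 20 for independent groups of normal values. The values at the listed sites fell in separate bands, as described below, and some groups shared sites. That rate therefore cannot decide whether 29 is more than chance gives. The cow apart was MRG replicate 4 in 8 of the 29 groups and MSG replicate 6 in 5. The 8 include IFNAR1, GART, SYNJ1 and the chromosome 1 window around them, which share sites. At the named tiles, MRG replicate 2 was at 42.6% near LOC112447179, MRG replicate 5 at 81.0% near LOC505199, MRG replicate 3 at 35.3% at OR8B1ASP, and MSG replicate 6 at 15.1% at IGSF21 and 68.9% at MGAT5.

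Over the averaged sites of named genes, the cows apart among those with dense or promoter sites were MRG replicate 3 for MYL10 (46.4%), MRG replicate 4 for MIR10165 (45.6%) and TMEM18 (54.5%), MSG replicate 5 for EPHA8 (42.9%) and ENOPH1 (19.8%), MRG replicate 5 for TBCK (54.7%) and MSG replicate 1 for GLRX5 (26.1%). Among list genes they were MSG replicate 5 for CXCR4 (49.1%), MRG replicate 3 for MAP3K7 (44.9%), MRG replicate 4 for MASP1 (44.2%) and LEF1 (0%), MSG replicate 4 for C8A (80.0%), MSG replicate 3 for DLK1 (83.0%) and MRG replicate 2 for CEBPD (0%) and CLEC4E (51.4%). They were also MSG replicate 6 for THEMIS (48.4%) and SPTB (55.4%), and MRG replicate 6 for GYPC (2.99%). MRG replicate 6 also stood apart in the median over the erythroid and platelet list (37.5%). On chromosome 1, MRG replicate 4 stood apart over the sites of IFNAR1 (0%), GART (0%) and SYNJ1 (58.3%) and over the lower sites of the 1 Mb window around them (24.6%).

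Values at the listed sites fell at exactly 0, near the middle and near the top. Among cow values 21.7% were exactly 0, 0.588% lay above 0 and up to 10%, and 17.0% were exactly 100. The part of sequencing depth in these shares was not tested, because depth was not used. At 106440 sites (54.2%) every cow was at or below 5%, between 25% and 75%, or above 75%. At each of them at least 1 cow was in the lowest band. Sequence variants at the site may account for this but were not shown. At these sites the share of middle values was 37.8% in MSG and 37.7% in MRG, against 38.4% and 38.8% under random mating. The largest gap was 1.12 percentage points. The 200 tiles (16.3%) with the same bands met the same bound, with a gap of 2.44 points. Those tiles were picked for the same pattern, so they are no contrast. Variants and other sources were therefore not told apart. Methylation of whole neighbourhoods changing together was not argued against. Among sites with a difference of at least 40 points, those with a cow at 0 lay in listed tiles 2.16 times as often as those without (interval 1.51 to 3.26). A tile averages the same reads, so a site at 0 from a variant would also move its own tile. The ratio therefore does not favour this explanation over variants. Methylation set by the haplotype a cow carries would give the same random-mating shares and cannot be told apart from variants without genotypes. Neighbouring pairs with a cow at 0 at both moved in opposite ways in 5.67% of cases, between the bounds set. That share was 0.227% for pairs with no cow at 0 and 15.9% for pairs with a cow at 0 at 1 of them. The biological difference between the groups stays open as well.

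None of the listed sites passed the per-cow test although every one had passed the authors' test. Whether 12 cows are too few for this many sites was not decided. Simulated differences of 35 points were recovered at 0% when 200 of 196275 sites changed. The rate was 27.5% when 101964 changed, as many as had an unadjusted p under 0.05, and lay between the bounds set. The simulated values lacked the values at 0 and the correlation of neighbours. The 31207 passing sites among the 42667 with no cow at 0 do not bear on this question, because both selections used the values that were tested. Authors' p values that leave out the spread between cows may contribute, but the test was not decisive: with the difference held, their rank correlation with the within-group SD across sites was -0.139 with the difference of cow means and -0.297 with the authors' difference, and the prediction had not said which. For limma's p across sites, with the difference of cow means held, the correlation was -0.745. Across tiles the same correlations were -0.0839 and -0.134 for the authors' p values, against -0.917 for limma's p. The biological difference between the groups was not tested by either.

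Other splits of the 12 cows do not decide whether chance can be excluded, because the rows had been selected on the real split. For sites the count says nothing, since all 100 of 100 splits must reach the real count of 0; the highest other count was 411, at an unadjusted p under 0.05 the real split gave 101964 sites and the highest other 39339, as selection on the real split would favour, and a structure among the cows beyond the groups was not tested. For tiles 1 split, the real one with 899, gave as many, and the highest other count was 6.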

How the results depend on the processing

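Leaving out rows with a cow at exactly 0 and counting each CpG once were chosen after seeing the data, the other alternatives before. Of the sites, 0 passed limma's test on the logit scale, at a threshold of 0.01, with all 12 cows and by exact permutation. The count was 0 to 74 with single cows left out, highest without MSG replicate 6, and 31207 of 42667 without rows with a cow at 0; the cause was not tested. Of the tiles, 899 passed, with 621 on the logit scale, 771 with all 12 cows and 919 without rows with a cow at 0. The count was 397 to 797 with single cows left out, 213 by exact permutation, for which the cause was not tested, and 0 at a threshold of 0.01, where the lowest adjusted p was 0.0347. The share of sites higher in MSG was 50.9% and that of tiles 54.3% at 40 points or more. Both were over fewer rows, with intervals that took in an even split. In other settings the shares ran from 52.2% to 57.3% for sites and 56.1% to 56.5% for tiles. An authors' q-value under 0.001 kept all 1227 tiles, so for tiles that setting repeats the main result. The promoter difference of 1.76 points turned to -0.547 within 1 kb and -1.25 without rows with a cow at 0, and was 0.668 with 1 site per run; the cause was not tested. No gene list passed in any of 5 settings, and 12 of 16 changed side against other genes in at least 1; the cause was not tested. The 12 named tiles passed in 138 of 144 tests with a cow left out, and of the 46 named genes past the adjusted threshold 31 lost it in at least one, while 18 of the others gained it in at least one. Without rows with a cow at 0, 36 named genes had a value, of which 3 lost and 7 gained it. Only sites of a gene's more frequent direction were kept there, so no gene could change direction. Some genes without a value had sites with no cow at 0, all of the other direction, as VWF, MASP1, IL10RB, IFNAR1 and CLEC4E did. Neither the direction of the named tiles and genes nor the tiles' passes speak for stability. The tiles were chosen for no overlap, and each gene averages sites of one direction. No paired analysis was run, because the labels pair no cows and the replicate numbers only follow the order of the records. Depth was not used, so no minimum coverage was varied.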

Other observations

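The test reported in this part was chosen after its window was seen. On chromosome 1, the window from 2000001 to 3000000 includes the genes of the interferon and interleukin 10 receptor cluster. Of its 403 listed sites, 350 (86.8%) were lower in MSG, against a median of 49 listed sites per window of 1 Mb over 2642 windows. The most of these lower sites were annotated to C1H21orf62 (78) and OLIG2 (75). IL10RB had 51 of 53 sites lower in MSG (18.0% ± 22.4 in MSG against 52.6% ± 30.9 in MRG, SD, n = 6 each) and IFNAR1 had 37 of 42 lower (37.6% ± 32.7 against 73.9% ± 36.5), whereas IFNGR2 had 14 of 19 higher (76.8% ± 26.8 against 44.1% ± 39.0). These genes, except IL10RB, were chosen after their values were seen. Over the 350 lower sites the cows averaged 38.6% ± 34.5 in MSG and 75.8% ± 25.2 in MRG (exact permutation p = 0.0563, two-sided, 1 window chosen from 2642). The MSG cows ranged from 0.153% to 83.8% and the MRG cows from 24.6% to 91.2%, and 95.5% of the window's sites had a cow at exactly 0.

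Listed sites were unevenly spread. The 132 windows with the most sites held 21% of all listed sites, and the fullest, with 948 sites, lay on chromosome 2 from 134000001 to 135000000 and included IGSF21. A window on chromosome 18 from 62000001 to 63000000 with genes of natural killer cell receptors held 439 sites, 40.8% of them higher in MSG. In it KIR3DL1 had 10 of 11 sites lower in MSG (19.8% ± 21.5 against 59.3% ± 21.1), KIR2DS1 had 6 higher and 6 lower, and NCR1 had 11 of 14 higher; KIR3DL1 and KIR2DS1 were chosen after their values were seen.

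Both strands of one CpG were listed at 43073 of 153202 CpGs. Where a cow was at exactly 0 on either strand, it was at 0 on both in 96.5% of 122402 cases. Neighbouring CpGs within 200 bases correlated across cows with a median r of 0.927 over 2202 pairs with no cow at 0, 0.955 over 13062 pairs with a cow at 0 at both, and 0.236 over 1670 pairs with a cow at 0 at 1 of them; these are medians across pairs, which are not independent.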
